A study of Mus musculus with 12 samples.

How the data were processed

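Brain cells of 9 mice were profiled: 3 mice without tumour, 3 mice collected on day 17 and 3 mice collected on day 23 after 4T1Br4 mouse mammary carcinoma cells had been placed in the mammary fat pad. Brain cells had been sorted by CD45, a surface protein of leukocytes, and every mouse had its own tag of 2 kinds, an antibody-bound oligonucleotide (TotalSeq-C) and a lipid-anchored oligonucleotide (MULTI-seq), so that cells of all 9 mice shared 1 droplet capture per sorted fraction. Of 12 labelled libraries, 5 were used: the gene expression library of CD45-negative brain cells, and the TotalSeq and MULTI-seq tag libraries of the CD45-negative and CD45-positive brain cells. Gene expression of CD45-positive brain cells, the dura libraries and the calvarium libraries were not analysed here.

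The deposited values were raw UMI counts per gene or tag and per barcode, before any calling of cells. Per the labels, the libraries followed the 10x 5' single-cell chemistry. Per the submitters' processing notes, Cell Ranger and the mm10 mouse genome were used to make the counts. The Cell Ranger version and the gene annotation were not given in the sources used here. A step that splits reads between near-identical genes is not recorded either, so values of Hspa1a and Hspa1b, of Serpina3i, of Ly6c1 and Ly6c2 and of the H2-Q genes are uncertain.

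A cell was kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Tags were called with HTODemux in Seurat 5.3.0 (R 4.3.3) at a positive quantile of 0.99. Cells with more than 1 tag of the kind that set the animal were left out as doublets. More than 1 tag of the other kind alone did not remove a cell. The kind of tag that gave more single-tag cells was to set the animal, a rule chosen before the data were examined; this was MULTI-seq, with 6349 single-tag cells against 5820 by TotalSeq. A deposited tag reference pairs MULTI-seq and TotalSeq tags with animals. Its TotalSeq names and the tag names in the matrices differ by 1 tag, so that 6 of the TotalSeq tags taken by name fall on another animal than their MULTI-seq partner does and 1 has no named animal. The MULTI-seq names were used throughout, and the TotalSeq names taken literally, which leave 8 mice with 2 controls, were tried as an alternative. Scrublet, at an expected doublet rate of 0.08, marked 0 of 7811 cells and so did not work, and doublets rest on tags alone.

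Cells were clustered in scanpy 1.11.5 (Python 3.11.15) on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2). Clusters were named as like a cell class from 25 marker lists fixed before the data were examined; a cluster led by markers of another class stayed unnamed. Endothelial-like cells were clustered again and named by arterial, capillary, venous and fenestrated markers, and subclusters without clear markers stayed unnamed. Genes called in any endothelial-like comparison, the genes of 11 lists of responses and mitochondrial genes were left out of that clustering. Lcn2, Vcam1, Tmem252, Ackr1 and those capillary markers that changed between conditions were left out of the naming score too. They still counted in a check of leading genes that could leave a cluster unnamed. Choices made after the data were seen were these exclusions, the removal of haemoglobin genes from the variable genes, and the requirement that a leading gene of a cluster have a UMI in at least 10% of its cells.

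UMI counts were summed per mouse and cell class, and a sum of fewer than 20 cells was left out. Sums were tested with the quasi-likelihood test of edgeR 4.0.16, with TMM normalisation and filterByExpr, with all 9 mice and the 3 conditions in 1 model, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The mouse was the replicate, never the cell. Levels are CPM after TMM scaling, as mean ± SD over mice, and log2 fold changes are given with a standard error (SE) taken as the size of the change over the square root of the test's F value. Class comparisons kept the mouse as a block, and that of endothelial-like with pericyte-like cells also asked for an absolute log2 fold change over 1. Shares of cells were compared with a two-sided exact permutation test, which cannot go below p = 0.10 with 3 mice against 3.

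Gene lists (22, fixed before the data were examined) were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and with fry. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Named genes were chosen by a rule fixed beforehand: per comparison, the 10 genes of largest fold per direction among called genes whose mice did not overlap between the groups, and per list the up to 4 members of smallest p; where fewer than 10 genes passed, the 10 of smallest p. Between classes the rule took genes of mean CPM of at least 50 that were no marker, of which those without a group at 0 are printed. Smooth muscle-like and choroid plexus epithelial-like comparisons, tests of differences between classes, fits on endothelial subclasses, and lists of protein folding, heat shock, immediate early and clock genes were added after the data had been seen. Gene positions are from the GENCODE vM21 annotation of mm10.

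The CD45-negative matrix held 56980165 UMIs in 327088 barcodes. The filter kept 7811 cells, which held 94.0% of the UMIs, with a median of 4892 UMIs, 2180 genes and 1.99% mitochondrial UMIs. Counts per mouse and the spread between mice set the precision. In simulated data of the same depth and spread with 200 genes changed, the day 23 test in endothelial-like cells recovered 44.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold, among 10296 genes. The same shares were 8.07%, 38.5% and 87.3% in pericyte-like cells (2788 genes), 11.3%, 54.7% and 88.5% in smooth muscle-like cells (3998 genes) and 33.9%, 64.6% and 93.7% in choroid plexus epithelial-like cells (7880 genes). For the comparison of endothelial-like with pericyte-like cells, which asks for a change above 2-fold, they were 0%, 60% and 100% (8123 genes). Intervals are exact binomial 95% intervals and cover counting error only.

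Alternatives fixed beforehand were DESeq2 1.42.0 with its size factors, library size alone, RLE size factors, no filter on low counts, cell minimums of 500 UMIs with 250 genes and of 2000 UMIs with 1000 genes, at most 5% mitochondrial UMIs, TotalSeq tags, cells on which both kinds of tag match, a tag quantile of 0.95, MULTIseqDemux, Leiden resolutions of 0.5 and 2, and each mouse left out in turn. Alternatives added after the data had been seen were the TotalSeq names of the tag reference, the mouse number as a block, cells that neighbour tag doublets left out, and the subclass fits. Shares per tag without conditions, planned for the case that no source paired tags with conditions, were not needed.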

Results

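Gene expression was measured in single brain cells that had been sorted as negative for CD45, the leukocyte surface protein, which keeps blood vessel and other non-immune cells. The study's title concerns the blood vessel environment of the brain before metastases form. Of the 9 mice, 3 carried no tumour, 3 were collected on day 17 and 3 on day 23 after 4T1Br4 cells, a mouse mammary carcinoma line, had been placed in the mammary fat pad. The 7811 kept cells had a median of 4892 UMIs and 2180 genes, and 6349 of them carried the MULTI-seq tag of a single mouse. A further 1422 cells carried more than 1 such tag and 40 carried none. The sequences mCherry and NeoR, listed with the genes, had 0 UMIs in the whole matrix. With a limit of 3 counts where 0 were seen, the share of such cells with a UMI could be up to 0.0384%. This sets no limit on cells that carry the sequences without a UMI.

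Endothelial-like cells, which line blood vessels, made up most of the cells, with 383 to 660 cells per mouse. Pericyte-like cells, the contractile cells wrapped around capillaries, numbered 21 to 41 per mouse. Choroid plexus epithelial-like cells, which make cerebrospinal fluid, numbered 59 to 109, and smooth muscle-like cells of larger vessels numbered 17 to 49. Fibroblast-like cells (2 to 21 per mouse) and oligodendrocyte-like cells (0 to 2 per mouse) were too few to test. Summed UMIs per mouse in endothelial-like cells ranged from 1651464 to 2701624 in control mice, from 1891126 to 3000908 on day 17 and from 2718090 to 3055085 on day 23, so that each day 23 mouse was above each control mouse. Pericyte-like cells gave far fewer, from 70649 to 108722 UMIs per control mouse, from 95636 to 152843 on day 17 and from 125744 to 148493 on day 23.

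Each mouse had a tag of both kinds, so the animal called from 1 kind can be set against the other. Among 5256 CD45-negative cells with a single tag of each kind, 5241 fell on matching partners (99.7%, exact 95% interval 99.5 to 99.8, adjusted Rand index 0.994). Among 10290 CD45-positive barcodes with at least 50 tag UMIs the share was 98.2% (10106 barcodes, exact 95% interval 97.9 to 98.5, adjusted Rand index 0.966). By MULTI-seq, the mice gave 8.10% to 12.9% of the single-tag CD45-negative cells each. In the CD45-positive fraction they gave 4.46% (control mouse 1) to 15.9% (day 17 mouse 1). The partners are 1 to 1 at the level of cells, except by MULTIseqDemux in CD45-positive barcodes, but the tag reference names 6 of the TotalSeq tags for another mouse than their partner and 1 for no mouse. By those names 2 mice would change condition, and 8 mice would remain, 2 of them controls. All conditions below therefore rest on the MULTI-seq names of the reference.

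**Figure D1:**
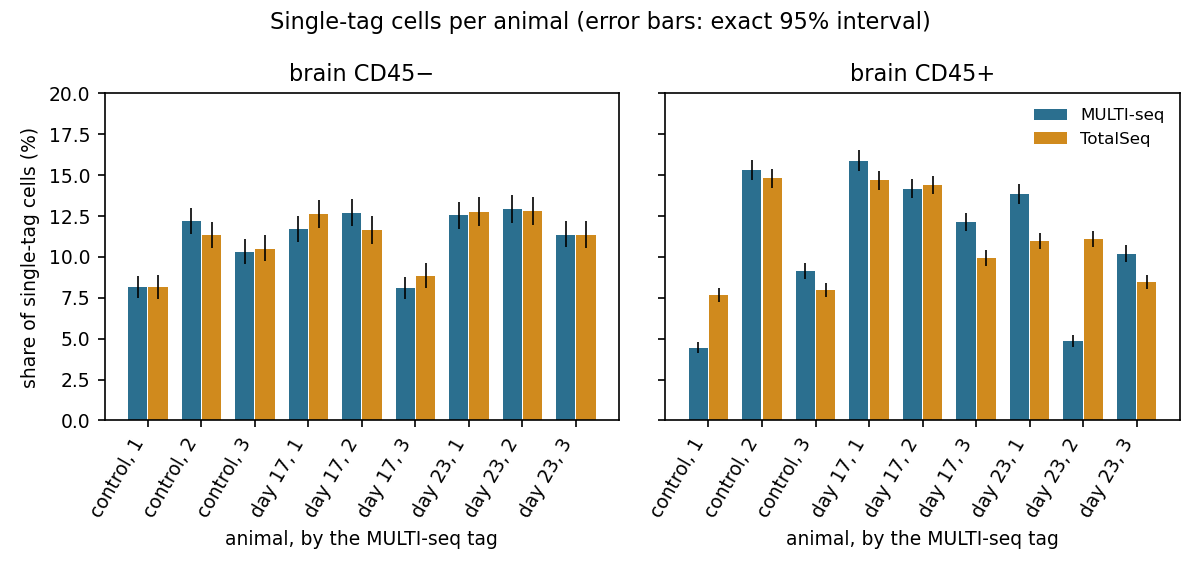
Share of single-tag cells (%, y axis) that each of the 9 mice (x axis) contributed, by MULTI-seq and by TotalSeq tags, in the CD45-negative and CD45-positive brain fractions, with bars for shares and error bars for exact 95% binomial intervals. In the CD45-negative fraction the MULTI-seq shares lie between 8.10% and 12.9%, and in the CD45-positive fraction between 4.46% and 15.9%.

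On day 17, endothelial-like cells of tumour-bearing mice held more RNA of genes induced in acute inflammation than those of control mice. Lcn2, which encodes the iron-scavenging acute-phase protein lipocalin-2, was at 224 ± 121 CPM against 18.1 ± 15.2 in control mice (mean ± SD, n = 3 mice each), a log2 fold change of 3.66 ± 0.54 (SE). Vcam1, the endothelial receptor for leukocyte integrins, rose from 88.8 ± 21.5 to 197 ± 20.4 CPM (log2 1.13 ± 0.13). Plaur, the urokinase receptor, rose by 1.15 ± 0.18 on the log2 scale, Il1r1, the interleukin-1 receptor, by 1.07 ± 0.22, and Tnfrsf12a, the receptor of the cytokine TWEAK, by 0.79 ± 0.12. Cirbp, a cold-inducible RNA-binding protein, fell from 89.8 ± 5.70 to 62.8 ± 6.12 CPM, and Clec14a, an endothelial surface lectin, fell from 192 ± 7.46 to 141 ± 11.2 CPM. In capillary-like cells alone Clec14a was at -0.05 ± 0.15 on the log2 scale. It was at -0.51 ± 0.20 in arterial-like and -0.29 ± 0.13 in venous-like cells alone, and passed in none of these subclasses.

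Of 10377 genes tested in endothelial-like cells, 36 passed on day 17 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 30 higher and 6 lower; with library size alone the split was 23 to 11. The other risers of large fold were Serpina3i, a serine protease inhibitor with near-identical copies (log2 2.15 ± 0.32), the secretoglobin Scgb3a1 (1.45 ± 0.26), Tmem252 (1.23 ± 0.24), the transcription factor Maff (0.87 ± 0.11) and Litaf (0.82 ± 0.14). The remaining 4 genes that fell were Mpv17l2 (-0.61 ± 0.11), Thap3 (-0.45 ± 0.09), Zic2 (-0.41 ± 0.08) and Rsrp1 (-0.37 ± 0.07). Adjusted p values of the named genes by edgeR with Benjamini-Hochberg adjustment ran from 0.00054 for Vcam1 to 0.049 for Il1r1. Lcn2 lies at positions 32384633 to 32388252 of chromosome 2 and Vcam1 at 116109949 to 116129688 of chromosome 3 (mm10), both annotated as protein coding.

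Among the fixed lists on day 17, 3 of 18 measured acute inflammatory genes rose (Lcn2, Il1r1 and Cebpd, a transcription factor of the acute phase, log2 0.65 ± 0.12), and 13 rose adjusted over the list alone, with a median log2 fold change of 0.57. Camera gave this list a Benjamini-Hochberg adjusted p = 7.4e-20 with the preset correlation and adjusted p = 0.010 with an estimated correlation. Of 11 leukocyte adhesion genes, Vcam1 rose over all genes and 4 rose adjusted over the list alone. Its camera test gave a Benjamini-Hochberg adjusted p = 5.8e-08, and adjusted p = 0.010 with an estimated correlation. Icam1, another leukocyte receptor, was at 252 ± 77.1 CPM against 126 ± 30.9, which did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.081; log2 -0.14 in capillary-like cells alone). Of 15 hypoxia and glycolysis genes, the lactate dehydrogenase gene Ldha rose (0.41 ± 0.06) and 8 rose adjusted over the list alone, with a median of 0.33. The camera test of these genes gave a Benjamini-Hochberg adjusted p = 1.1e-09, and adjusted p = 0.083 with an estimated correlation. Of 15 glucocorticoid response genes, Lcn2 and the cell cycle inhibitor Cdkn1a rose (0.56 ± 0.11 for Cdkn1a) and 8 rose adjusted over the list alone. Camera gave them a Benjamini-Hochberg adjusted p = 1.1e-10, and adjusted p = 0.11 with an estimated correlation. Lcn2 and Nfkbia stand in the acute inflammatory list too.

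The 24 interferon response genes had a median log2 fold change of -0.21 on day 17, with 0 past the threshold over all genes and 4 lower adjusted over the list alone. For the whole list camera gave a Benjamini-Hochberg adjusted p = 2.2e-06, and adjusted p = 0.24 with an estimated correlation. The 13 class I antigen presentation genes had a median of -0.19 with 0 past either threshold. By camera the list had a Benjamini-Hochberg adjusted p = 0.017, and adjusted p = 0.53 with an estimated correlation. Preset camera also called the angiogenesis list (Plaur rose, 4 of 15 adjusted over the list alone, median 0.01), the basement membrane list (0 and 4 of 16, median 0.16) and the immediate early and heat shock list (Hspa8 rose, 2 of 21 adjusted over the list alone, median 0.07), at Benjamini-Hochberg adjusted p = 0.0077, 0.017 and 0.016. With an estimated correlation these were adjusted p = 0.16, 0.17 and 0.53. Blood-brain barrier transport genes (0 of 20; 2 higher and 1 lower adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.12) and tight junction genes (0 of 12; 1 lower adjusted over the list alone; adjusted p = 0.32) were not called. Cldn5, the main tight junction claudin of brain vessels, was at 3042 ± 159 CPM against 3528 ± 183 in control mice, which did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.17).

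Lcn2, Vcam1 and Tmem252 are also among the fixed markers of venous endothelium, while the other venous markers Slc38a5 (log2 0.43 ± 0.10), Nr2f2 (-0.07), Vwf (0.42), Ackr1 (2.02) and Ephb4 (-0.12) did not pass on day 17. Without venous-like cells 16 genes passed, 15 of them shared with the 36, but 15 of 20 named genes lost their call, at adjusted p from 0.053 to 0.95 by edgeR with Benjamini-Hochberg adjustment. The change was smaller by more than 2 SE for Lcn2 (1.84 ± 0.51), Vcam1 (0.11 ± 0.25) and Serpina3i (0.36 ± 0.36). For the other 12 it lay within 2 SE of the full one, as for Il1r1 (0.72 ± 0.24), Cebpd (0.56 ± 0.15), Tmem252 (1.07 ± 0.27), Cirbp (-0.47 ± 0.11) and Clec14a (-0.49 ± 0.10). In venous-like cells alone Lcn2 (3.82 ± 0.52), Vcam1 (1.64 ± 0.18), Il1r1 (1.27 ± 0.24) and Cebpd (0.91 ± 0.14) passed. Of 20 named genes past the threshold, 7 passed with each mouse left out in turn (Lcn2, Serpina3i, Plaur, Vcam1, Maff, Tnfrsf12a and Ldha), and the count was 17 without control mouse 1 and 22 without control mouse 2. DESeq2 called 64 genes, the absence of a filter on low counts gave 311, and the literal TotalSeq names, which leave 2 control mice, gave 4.

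On day 23, genes of the heat shock response rose in endothelial-like cells. Hsph1, a large chaperone that assists Hsp70, was at 171 ± 16.9 CPM against 48.2 ± 11.7 in control mice (mean ± SD, n = 3 mice each; log2 fold change 1.79 ± 0.16 SE). Hsp90aa1, the inducible Hsp90 chaperone, rose from 304 ± 36.0 to 637 ± 60.8 CPM, and Hspa8, the constitutive Hsp70, from 2191 ± 278 to 4038 ± 344 CPM. The leukocyte receptors rose as well. Icam1 was at 337 ± 91.0 CPM against 126 ± 30.9 (log2 1.40 ± 0.22). Vcam1 was at 150 ± 13.7 against 88.8 ± 21.5 (0.73 ± 0.13), and Sele, the E-selectin gene, at 15.4 ± 11.8 against 0.764 ± 0.730 (4.10 ± 0.77). Cirbp was lower again, at 50.3 ± 3.56 against 89.8 ± 5.70 CPM (log2 -0.83 ± 0.10).

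Of the same 10377 genes, 201 passed on day 23 by edgeR with Benjamini-Hochberg adjustment, 166 higher and 35 lower; with library size alone the split was 101 to 77. Other risers of large fold were the proto-oncogene Myc (log2 1.91 ± 0.45), the clock output genes Dbp (1.73 ± 0.25) and Nr1d1 (1.48 ± 0.16), and Hspa4l, an Hsp110 chaperone (1.36 ± 0.18). They also included Tnfaip3, an inhibitor of NF-kappaB signalling (1.35 ± 0.21), Rgs16, a regulator of G protein signalling (1.34 ± 0.19), and Hspa1b, the inducible Hsp70 with the near-identical copy Hspa1a (1.32 ± 0.25). The largest falls were in Fam102b (-1.83 ± 0.45), Nsg2 (-1.55 ± 0.25), Haghl (-1.29), Rnf152 (-1.23), Ralgps2 (-1.19), Trp53i11 (-1.12), Zfp688 (-1.06), Tlcd2 (-0.86) and Thrsp (-0.86 ± 0.17). By edgeR with Benjamini-Hochberg adjustment, adjusted p ran from 1.2e-05 for Hsp90aa1 to 0.049 for Fam102b. Hsph1 lies at 149614287 to 149636376 of chromosome 5, Hspa8 at 40800984 to 40810087 of chromosome 9 and Cirbp at 80165985 to 80172786 of chromosome 10 (mm10), all annotated as protein coding.

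**Figure D2:**
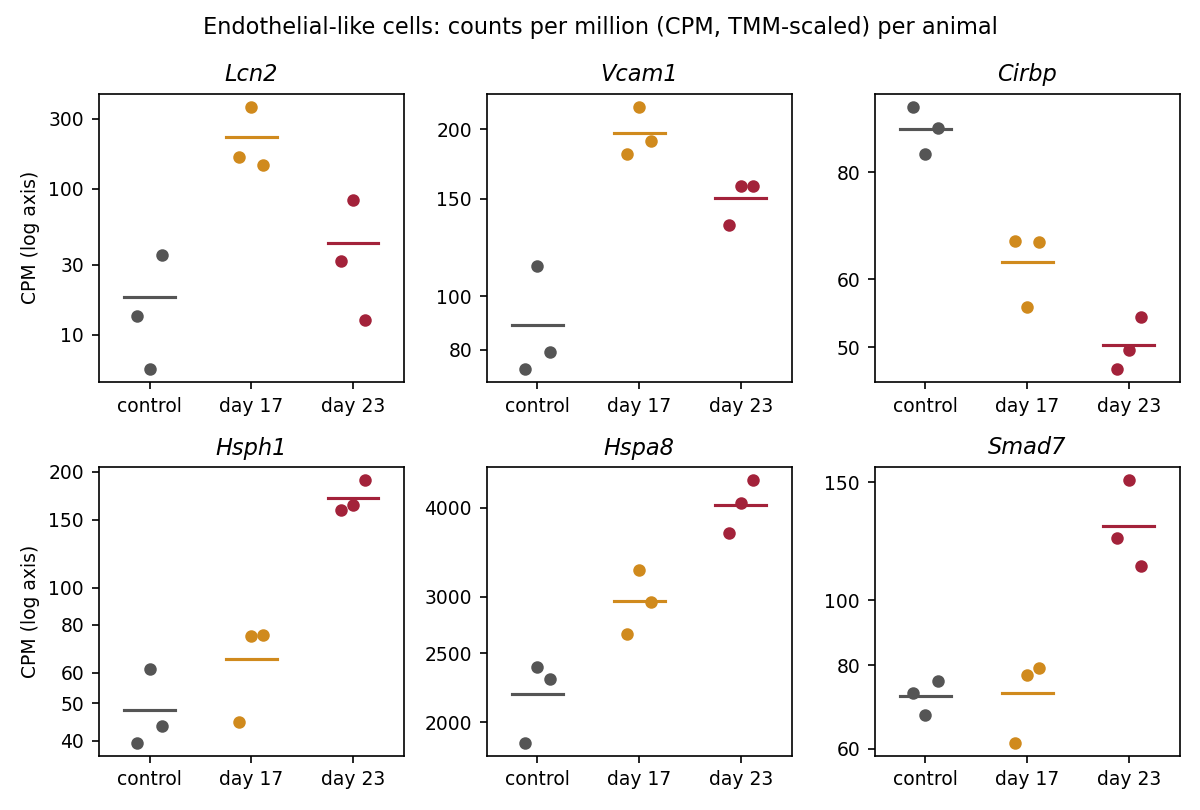
TMM-scaled CPM (log axis) of Lcn2, Vcam1, Cirbp, Hsph1, Hspa8 and Smad7 in endothelial-like cells of control, day 17 and day 23 mice, with points for the 3 mice of each group and lines for the means. Mean Lcn2 was 18.1, 224 and 42.4 CPM in control, day 17 and day 23 mice, while mean Hsph1 was 48.2, 65.0 and 171 CPM and mean Cirbp 89.8, 62.8 and 50.3 CPM.

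Among the lists on day 23, 12 of 21 immediate early and heat shock genes rose and 17 rose adjusted over the list alone, with a median log2 fold change of 0.41. Its camera test gave a Benjamini-Hochberg adjusted p = 4.6e-32, and adjusted p = 0.028 with an estimated correlation. Besides the chaperones these included Ier3, an immediate early gene of stress (0.69 ± 0.08). Of 18 acute inflammatory genes 7 rose and 12 rose adjusted over the list alone, among them Tnfaip3, Cebpd (0.61 ± 0.12), the oncostatin M receptor gene Osmr (0.45 ± 0.08) and Socs3, a feedback inhibitor of cytokine signalling (0.54 ± 0.10). The median was 0.58. The camera test of these genes gave a Benjamini-Hochberg adjusted p = 3.1e-18, and adjusted p = 0.021 with an estimated correlation. Of 11 leukocyte adhesion genes Icam1, Vcam1 and Sele rose, and 3 rose adjusted over the list alone. For the whole list camera gave a Benjamini-Hochberg adjusted p = 3.1e-05, and adjusted p = 0.026 with an estimated correlation. Of 18 TGF-beta and mesenchymal genes 4 rose, namely the BMP and TGF-beta target genes Smad7 (0.85 ± 0.11), Id1 (0.56 ± 0.08), Id2 (0.59 ± 0.10) and Id3 (0.33 ± 0.07). Counted by p values adjusted over the list alone, 6 rose and 1 fell. By camera the list had a Benjamini-Hochberg adjusted p = 1.9e-05, and adjusted p = 0.026 with an estimated correlation.

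**Figure D3:**
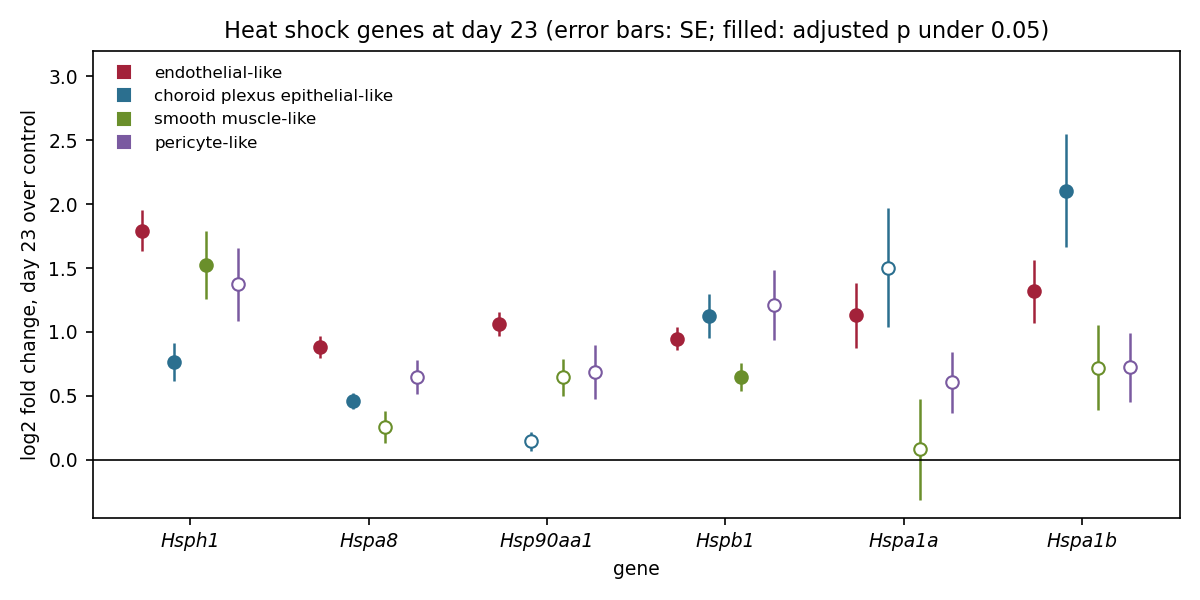
Log2 fold change from control to day 23 mice (y axis) of Hsph1, Hspa8, Hsp90aa1, Hspb1, Hspa1a and Hspa1b (x axis) in endothelial-like, pericyte-like, smooth muscle-like and choroid plexus epithelial-like cells, with error bars for the SE and filled points for edgeR Benjamini-Hochberg adjusted p under 0.05. Hsph1 was at 1.79 ± 0.16 in endothelial-like cells, at 1.37 ± 0.29 in pericyte-like cells, where it did not pass, and at 1.52 ± 0.27 in smooth muscle-like cells.

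Of 20 blood-brain barrier transport genes 3 rose on day 23 and 8 rose adjusted over the list alone, with a list median of 0.18. The 3 were the transferrin receptor gene Tfrc (log2 0.46 ± 0.07), the lipid transporter gene Mfsd2a (0.40 ± 0.08) and the amino acid transporter subunit gene Slc3a2 (0.28 ± 0.07). Its camera test gave a Benjamini-Hochberg adjusted p = 9.9e-06, and adjusted p = 0.11 with an estimated correlation. Of 15 hypoxia and glycolysis genes Ldha (0.50 ± 0.06) and Ankrd37 (0.73 ± 0.15) rose, and 7 rose adjusted over the list alone. The camera test of these genes gave a Benjamini-Hochberg adjusted p = 4.4e-06, and adjusted p = 0.11 with an estimated correlation. The 13 class I antigen presentation genes had a median of -0.30, with 0 past the threshold over all genes and 5 lower adjusted over the list alone. For the whole list camera gave a Benjamini-Hochberg adjusted p = 3.1e-05, and adjusted p = 0.36 with an estimated correlation. Preset camera also called the angiogenesis list (Plaur, 1.03 ± 0.18 but -0.07 in capillary-like cells alone, and the VEGF receptor gene Flt1, 0.28 ± 0.05, rose; 3 of 15 adjusted over the list alone), the Notch list (0 and 3 of 8) and the Wnt list (0 and 3 of 18), at Benjamini-Hochberg adjusted p = 0.016, 0.023 and 0.045, each at adjusted p = 0.12 with an estimated correlation. Cxcl12, a chemokine listed with the metastatic niche factors and the chemokines, rose by 0.35 ± 0.06 and the adherens junction gene Ctnna1 by 0.30 ± 0.06. Camera called neither the niche list (Benjamini-Hochberg adjusted p = 0.42), the chemokine list (0.067), the adherens junction list (0.83) nor the tight junction list (0.053).

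Of 40 named genes past the threshold on day 23, 22 passed with each mouse left out in turn, among them Hsph1, Hsp90aa1, Hspa8, Icam1, Vcam1, Sele, Smad7, Id1, Id2, Tfrc, Nr1d1 and Cirbp. Mfsd2a, Cxcl12, Socs3 and Hspa1b were lost without control mouse 1 and Thrsp without day 23 mouse 1. Without venous-like cells Vcam1 (0.54 ± 0.23), Osmr, Ctnna1, Slc3a2, Rnf152, Fam102b, Zfp688 and Tlcd2 did not pass, each with a change within 2 SE of the full one. The count was 98 without control mouse 1, 129 without day 23 mouse 2, 506 without a filter on low counts, 49 in capillary-like cells alone and 30 by the literal TotalSeq names.

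Between day 17 and day 23, chaperone genes and the BMP and TGF-beta target genes Smad7, Id1, Id2 and Id3 rose in endothelial-like cells while Lcn2 fell. Hspb1, a small heat shock protein, was at 4227 ± 395 CPM on day 23 against 2270 ± 212 on day 17 (mean ± SD, n = 3 mice each; log2 fold change 0.90 ± 0.09 SE). Hsph1 rose by 1.40 ± 0.15 on the log2 scale. Smad7, an inhibitor of TGF-beta signalling, was at 129 ± 19.8 against 72.6 ± 9.81 CPM (0.84 ± 0.11) and Tfrc at 344 ± 20 against 203 ± 3.38 (0.76 ± 0.08). Lcn2 was at 42.4 ± 36.3 CPM on day 23 against 224 ± 121 on day 17 (log2 -2.40 ± 0.44). Vcam1 (-0.40 ± 0.12) and Icam1 (0.43 ± 0.21) did not pass, at adjusted p = 0.20 and 0.55 by edgeR with Benjamini-Hochberg adjustment, and Vcam1 was at 0.43 ± 0.22 without venous-like cells.

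In this comparison 63 of 10377 genes passed by edgeR with Benjamini-Hochberg adjustment, 52 higher and 11 lower on day 23. The other named risers were Hspa1b (log2 1.95 ± 0.25) and Hspa1a (1.58 ± 0.26), Rgs16 (1.39 ± 0.19), Dbp (1.17 ± 0.23), Nr1d1 (0.94 ± 0.15), Hspa4l (0.91 ± 0.16) and Hsp90aa1 (0.88 ± 0.09). Those that fell were Angptl4, a secreted inhibitor of lipoprotein lipase (-1.03 ± 0.21), the peroxisome gene Pex2 (-0.92 ± 0.16), Txnip, an inhibitor of thioredoxin (-0.75 ± 0.12), and the sphingosine-1-phosphate receptor gene S1pr1 (-0.58 ± 0.13). Falls of smaller size were in Ddah1 (-0.53 ± 0.09), Cdkn1a (-0.53 ± 0.11), Ralb (-0.47 ± 0.08), the caveolin gene Cav1 (-0.40 ± 0.07) and the cold-inducible RNA-binding gene Rbm3 (-0.38 ± 0.08). By edgeR with Benjamini-Hochberg adjustment, adjusted p ran from 8.6e-05 for Hspb1, Hsp90aa1 and Tfrc to 0.049 for S1pr1. Smad7 lies at 75367529 to 75395935 of chromosome 18 and Tfrc at 32608920 to 32632794 of chromosome 16 (mm10), both protein coding.

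Of 18 TGF-beta and mesenchymal genes 4 were higher on day 23 than on day 17 (Smad7, Id1 0.47 ± 0.08, Id2 0.67 ± 0.10 and Id3 0.45 ± 0.07). By p values adjusted over the list alone 7 rose and 1 fell, with a median log2 fold change of 0.19. Ccn2 of this list fell in capillary-like cells alone (-1.33 ± 0.22; edgeR, Benjamini-Hochberg adjusted p = 0.00038). It was at -1.15 ± 0.38 in venous-like and -2.34 ± 1.16 in arterial-like cells alone, where it did not pass. By camera the list had a Benjamini-Hochberg adjusted p = 5.0e-06, and adjusted p = 0.033 with an estimated correlation. Of 21 immediate early and heat shock genes 9 rose and 15 rose adjusted over the list alone, with a median of 0.34. Its camera test gave a Benjamini-Hochberg adjusted p = 5.9e-28, and adjusted p = 0.079 with an estimated correlation. Of 15 glucocorticoid response genes Lcn2 and Cdkn1a fell, and 1 rose and 5 fell adjusted over the list alone. The camera test of these genes gave a Benjamini-Hochberg adjusted p = 2.6e-05, and adjusted p = 0.24 with an estimated correlation. Of 24 interferon response genes Irf9, a subunit of the interferon-activated ISGF3 complex, rose (0.44 ± 0.08) and 5 rose adjusted over the list alone. For the whole list camera gave a Benjamini-Hochberg adjusted p = 0.00088, and adjusted p = 0.35 with an estimated correlation. The Wnt list had Foxq1 higher (0.41 ± 0.07; 4 higher and 1 lower of 18 adjusted over the list alone). The barrier transport list had Tfrc and Slc7a1, an arginine transporter gene (0.37 ± 0.07), higher (3 of 20 adjusted over the list alone). For Wnt and barrier transport camera gave Benjamini-Hochberg adjusted p = 0.0014 and 0.00088, and adjusted p = 0.079 and 0.24 with an estimated correlation.

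Lists lower on day 23 than on day 17 by preset camera were oxidative phosphorylation (0 of 20 past either threshold, median -0.08) and basement membrane (1 higher, Sparcl1 at 0.23 ± 0.05; 1 higher and 6 lower of 16 adjusted over the list alone), at Benjamini-Hochberg adjusted p = 0.0039 and 0.033. So were class I antigen presentation (0 of 13 past either threshold, median -0.22) and adherens junction and caveolae (Cav1 lower; 1 of 11 adjusted over the list alone), at Benjamini-Hochberg adjusted p = 0.033 and 0.048. In this order the 4 lists had, with an estimated correlation, adjusted p = 0.27, 0.24, 0.64 and 0.35. The Notch list was higher by preset camera (0 past the threshold and 1 of 8 adjusted over the list alone; Benjamini-Hochberg adjusted p = 0.034; adjusted p = 0.24 with an estimated correlation). The acute inflammatory list was not called: its median of -0.01 and mean of -0.13 lay below 0 while camera's direction was upward (Benjamini-Hochberg adjusted p = 0.49). In it Lcn2 was lower, and 4 higher and 2 lower of 18 were past the threshold adjusted over the list alone. Median, mean and camera direction also differed in sign for the leukocyte adhesion, angiogenesis, hypoxia and niche lists, none of which was called. Of 30 named genes past the threshold 13 passed with each mouse left out (Rgs16, Pex2, Ddah1, Id3, Hspb1, Hsph1, Jund, Nr1d1, Id2, Hsp90aa1, Tfrc, Hspa1b and Smad7). Lcn2 was lost without day 17 mouse 2, day 23 mouse 1 or day 23 mouse 3 and by DESeq2, and Hspa1a without day 17 mouse 1. Without venous-like cells Lcn2 (-2.00 ± 0.49), Ralb (-0.44 ± 0.11), Sparcl1 (0.19 ± 0.05), Flt1 (0.19 ± 0.05 against 0.23 ± 0.05) and Rbm3 (-0.34 ± 0.08) did not pass, each with a change within 2 SE of the full one. The count was 36 without day 23 mouse 3, 38 without day 17 mouse 1, 266 without a filter on low counts, 37 in capillary-like cells alone and 6 by the literal TotalSeq names.

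In pericyte-like cells 0 of 3003 genes passed in any of the 3 comparisons by edgeR with Benjamini-Hochberg adjustment or by DESeq2. Of these, 143, 157 and 204 genes had an unadjusted p under 0.05 for day 17 against control, day 23 against control and day 23 against day 17. On day 23 the genes of smallest p included chaperones. Hspe1, the mitochondrial co-chaperonin, was at 502 ± 120 CPM against 162 ± 40.4 in control mice (mean ± SD, n = 3 mice each; log2 1.66 ± 0.28). Hsp90ab1 was at 3686 ± 549 against 1961 ± 410, Hspa8 at 4212 ± 260 against 2687 ± 45.9 and Hsph1 at 484 ± 127 against 190 ± 74.2. P4ha1, a collagen prolyl hydroxylase subunit, was at 391 ± 18 against 135 ± 33.0 CPM, Nr1d1 at 227 ± 30.2 against 63.5 ± 26.6 and Rbm3 at 160 ± 47.1 against 372 ± 35.1. Their adjusted p by edgeR with Benjamini-Hochberg adjustment was 0.064 for Hspe1 and 0.090 for the others. Dnaja1 (1.07 ± 0.23), Hspb1 (1.21 ± 0.27) and Cebpb (-0.94) had adjusted p of 0.098, 0.14 and 0.23 by the same test.

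On day 17 the 10 pericyte-like genes of smallest p had an adjusted p of 0.96 by edgeR with Benjamini-Hochberg adjustment. They included the carbonic anhydrase gene Car4 (log2 0.73 ± 0.18), Pglyrp1, an antibacterial peptidoglycan receptor (2.27 ± 0.61), Heyl, a Notch target gene (-0.91 ± 0.25), the phosphodiesterase gene Pde4b (-1.03 ± 0.30) and Cxcl12 (-1.16 ± 0.36). Between day 17 and day 23 they included Hsph1 (1.31 ± 0.27), Rbm3 (-1.08 ± 0.25), Slco1a4 (-2.13 ± 0.51) and Pglyrp1 (-2.22), at adjusted p = 0.45 by the same test. Endothelial RNA in pericyte-like cells moved between the conditions, with a wide spread. The endothelial genes Slco1a4 and Cldn5 were at 305 ± 210 and 429 ± 312 CPM in pericyte-like cells of control mice. They were at 455 ± 286 and 596 ± 575 CPM on day 17 and at 106 ± 51.1 and 172 ± 164 CPM on day 23. The endothelial gene Emcn moved less. Pglyrp1 was itself far higher in endothelial-like than in pericyte-like cells, so its changes on both days cannot be told apart from those of endothelial RNA.

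No list was called in pericyte-like cells on day 17. On day 23 preset camera called blood-brain barrier transport (median log2 -0.48; 0 of 12 past either threshold) and acute inflammatory genes (median -0.57; 0 past the threshold and 1 of 6 lower adjusted over the list alone) as lower, both at Benjamini-Hochberg adjusted p = 0.019. With an estimated correlation these were adjusted p = 0.94 and adjusted p = 0.68. The immediate early and heat shock list, with 0 past the threshold and 3 of 20 higher adjusted over the list alone, was not called (median -0.08, mean 0.09, camera upward at Benjamini-Hochberg adjusted p = 0.61). Between day 17 and day 23 preset camera called barrier transport lower (median -1.29; 2 of 12 adjusted over the list alone), TGF-beta and mesenchymal genes lower (median -0.47; 0 of 10 past either threshold) and Notch genes higher (median 0.31; 2 of 6 adjusted over the list alone), at Benjamini-Hochberg adjusted p = 9.6e-07, 0.040 and 0.040. With an estimated correlation these were adjusted p = 0.69, 0.69 and 0.59. The barrier transport list holds endothelial genes such as Slco1a4. Its calls in both comparisons of day 23 cannot be told apart from changes of endothelial RNA in pericyte-like cells. Genes passed in some settings: on day 23 against control 14 with a minimum of 500 UMIs, 12 with a minimum of 2000 UMIs, 39 without a filter on low counts and 4, 1, 3 and 3 without day 17 mouse 1, day 17 mouse 3, day 23 mouse 1 and day 23 mouse 3. Without day 17 mouse 3, 1 gene passed on day 17 and 3 between both days, and without day 23 mouse 1, 2 passed between both days. In simulated data of this depth, with 200 of 2788 genes changed, the day 23 test recovered 38.5% of pericyte-like genes changed 2-fold. The share holds for that number of changed genes, and fewer were not simulated.

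No share of a cell class could pass a threshold of 0.05 with 3 mice against 3. Choroid plexus epithelial-like cells were 13.3% ± 2.47 of single-tag cells in control mice, 12.2% ± 1.35 on day 17 and 8.43% ± 0.670 on day 23 (mean ± SD, n = 3 mice each). Each day 23 mouse lay below each mouse of the other 2 groups. The two-sided exact permutation p was 0.10 for day 23 against control and against day 17, the smallest that 3 mice against 3 allow, with Benjamini-Hochberg adjusted values of 0.25 and 0.50. Pericyte-like cells were 4.04% ± 0.406, 4.75% ± 0.942 and 4.97% ± 0.178 (exact permutation p = 0.30, 0.10 and 0.80 for day 17 against control, day 23 against control and day 23 against day 17). Endothelial-like cells were 74.8% ± 3.32, 76.3% ± 1.61 and 78.9% ± 2.51 (exact permutation p = 0.60, 0.20 and 0.30). Smooth muscle-like cells were 4.56% ± 0.95, 4.09% ± 1.69 and 4.91% ± 1.87 (exact permutation p = 0.70, 0.90 and 0.60) and fibroblast-like cells 1.54% ± 1.16, 0.602% ± 0.187 and 1% ± 0.511 (0.40, 0.60 and 0.30). By TotalSeq tags the difference in the choroid plexus epithelial-like share between day 23 and control mice was -2.13 percentage points, against -4.87 by MULTI-seq.

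Endothelial-like and pericyte-like cells differed in 2264 of 8520 genes, 1322 higher and 942 lower in endothelial-like cells, by edgeR with Benjamini-Hochberg adjustment and a limit of 1 on the log2 scale. Away from the markers that named the classes, endothelial-like cells were higher in the organic anion transporter gene Slco2b1 (179 ± 18.6 against 9.01 ± 12.3 CPM, mean ± SD, n = 9 mice) and the heparan sulphate enzyme gene Hs3st1 (121 ± 25.7 against 4.60 ± 5.69). They were also higher in Ddah1 (96.7 ± 17.4 against 4.02 ± 8.33). Pericyte-like cells were higher in Sod3, the extracellular superoxide dismutase gene (4745 ± 531 against 4.58 ± 2.63 CPM), the amino acid transporter gene Slc6a20a, the purinergic receptor gene P2ry14 and the calsequestrin gene Casq2. The log2 difference was -9.99 ± 0.19 for Sod3 and -10.64 ± 0.18 for P2ry14. Of the barrier transport genes, 14 of 15 were higher in endothelial-like cells, over all genes and adjusted over the list alone (adjusted p = 0.095 with an estimated correlation). The clusters were drawn from the same counts, so these differences are not independent of how the classes were made.

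Within endothelial-like cells, arterial-like and venous-like cells differed in 1861 of 6112 genes, 959 higher and 902 lower in arterial-like cells, by edgeR with Benjamini-Hochberg adjustment. Pi16 (334 ± 93.1 CPM in arterial-like cells, n = 9 mice; log2 difference 8.85) and the matrix gene Fbln2 (220 ± 54.3 CPM; 7.81) were higher in arterial-like cells. Lrg1, a glycoprotein of the acute phase (303 ± 345 CPM in venous-like cells; -8.98), and Cd14, the co-receptor of lipopolysaccharide (226 ± 210 CPM; -5.96), were higher in venous-like cells. So were the apelin receptor gene Aplnr (76.1 ± 21.3 CPM; -6.42) and the carbonic anhydrase gene Car14 (90.0 ± 16.3 CPM; -5.41). All 7 measured Notch genes were higher in arterial-like cells (adjusted p = 0.014 with an estimated correlation). Of the others, 16 of 20 barrier transport genes and 10 of 13 acute inflammatory genes were lower there (each adjusted p = 0.049 with an estimated correlation). The same counts made the clusters here too, and genes such as Lcn2 and Ptgs2 led a venous-like cluster of 140 cells.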

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

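Tests of differences between cell classes, the tests of protein folding genes in choroid plexus epithelial-like cells the fit of venous-like cells alone, the share of venous-like cells and the sum of leukocyte markers of low baseline were chosen only after the results had been seen.

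Heat shock genes in endothelial-like cells were higher on day 23 than in control mice and than on day 17, and 63 genes differed between both days in their change from control (36 without day 23 mouse 3 and 38 without day 17 mouse 1). A difference in the mix of endothelial subclasses is argued against as the whole cause. The called heat shock genes had a median log2 fold change of 1.13 (SE 0.163) over all endothelial-like cells. In capillary-like, venous-like and arterial-like cells alone it was 1.51, 1.26 and 0.954. Capillary-like cells were named from 3 markers that did not lead their clusters, and some endothelial subclusters stayed unnamed. Stress of handling or dissociation stays open: immediate early genes, which such stress induces, had a median log2 fold change of 0.263 on day 23 (fry, Benjamini-Hochberg adjusted p = 0.0074), so handling may account for part of the rise. They were not called higher in the other classes of the same mice and library, with medians of -0.18 in pericyte-like (adjusted p = 0.52), -0.32 in smooth muscle-like (1 of 15 fell; adjusted p = 0.14) and 0.02 in choroid plexus epithelial-like cells (adjusted p = 0.58). Heat shock genes there had medians of 0.70, 0.45 and 0.62 (fry, Benjamini-Hochberg adjusted p = 0.038, 0.14 and 0.0064). Whether immediate early genes changed differently between the classes was not tested as a list. Time of day at collection cannot be told apart from the tumour's effect. All 7 clock genes chosen for this test beyond Nr1d1 and Dbp lay in the direction that a shift in time predicts. But 3 of them did so at an unadjusted p under 0.05 (edgeR, with Per2 at 1.36, Ciart at 0.91 and Tef at 0.84 on the log2 scale). Arntl, which such a shift would move opposite to Nr1d1, was at -0.36 (edgeR, unadjusted p = 0.053). Per1, a clock gene not among the 7, was lower on day 23 than on day 17 in endothelial subclasses. It was at -1.16 ± 0.29 in capillary-like, -0.99 ± 0.30 in venous-like and -0.66 ± 0.25 in arterial-like cells alone, where it did not pass. On day 17 against control it was at 0.65 ± 0.28, 0.50 ± 0.28 and 0.39 ± 0.25 there. An effect of the tumour on day 23 is the biological explanation that the design names, and it was not tested apart from these.

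Inflammatory genes (Lcn2, Il1r1, Vcam1 and Cebpd) were higher in endothelial-like cells on day 17, with a median log2 fold change of 1.10. Without venous-like cells the median was 0.639 (SE 0.243), above 0.5 of the full value but within its error, and none of the 4 genes passed (edgeR, Benjamini-Hochberg adjusted p from 0.17 to 0.95). Vcam1 went from 1.13 ± 0.13 to 0.11 ± 0.25, Lcn2 from 3.66 ± 0.54 to 1.84 ± 0.51, Il1r1 from 1.07 ± 0.22 to 0.72 ± 0.24 and Cebpd from 0.65 ± 0.12 to 0.56 ± 0.15. The calls of Vcam1 and Lcn2 ended with a change smaller by more than 2 SE, those of Il1r1 and Cebpd with one within 2 SE of the full change. A larger share of venous-like cells is argued against as the cause by their share of endothelial-like UMIs, 20.7% ± 0.18 on day 17 against 22.1% ± 2.26 in control mice (mean ± SD, n = 3 mice each; log2 ratio -0.092, SE 0.088). It is argued against also by venous-like cells alone, in which the median was 1.46 (SE 0.208); genes called in any comparison took no part in the clustering of these cells, but genes that vary with them did. Venous-like cells joined a subcluster of 717 cells and one of 140 cells, the latter with Lcn2 and Vcam1 among its leading genes. A shift between these subclusters could raise such genes at a constant venous-like share. It was not tested, and neither of the values above can decide on it. Whether the change differs between venous-like and other endothelial-like cells was not tested. A single day 17 mouse is argued against too, because the lowest median with a day 17 mouse left out was 0.920, without day 17 mouse 2. RNA of leukocytes is argued against, by a sum chosen after the results had been seen. The 36 leukocyte markers under 10 CPM in control mice summed to 10.1 ± 1.88 CPM on day 17 against 9.78 ± 2.05 in control mice (mean ± SD, n = 3 mice each). That is a rise of 0.322 CPM (SE 1.61), while the 4 inflammatory genes together rose by 633 CPM (SE 167). Among the 36, the 7 neutrophil markers rose by 0.718 CPM (SE 0.475), against 204 CPM (SE 68.8) for Lcn2. All leukocyte markers summed to 466 CPM on day 17 (444 to 478) against 424 CPM in control mice (399 to 456), mostly through Ly6c2, which other cells express as well. This sum was the test fixed beforehand, and it did not decide: the mean rose, but the mice of both groups overlapped. An effect of the tumour on day 17 is the biological explanation that the design names, and it was not tested apart from these.

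Protein folding genes of the endoplasmic reticulum were higher on day 23 in choroid plexus epithelial-like cells, with a median log2 fold change of 0.819 over the 8 called genes. Cells of high mitochondrial share are argued against as the cause, since the median was 0.828 with at most 5% mitochondrial UMIs. The 8 genes were called in the same cells, and other aspects of cell quality were not tested. Greater depth is argued against by the summed counts, which were above every control mouse in 0 of the day 23 mice. The pattern may be biological, as a hypothesis found and tested on the same data. By TotalSeq tags, however, 0 genes passed against 98, and the cause was not tested.

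Between choroid plexus epithelial-like and endothelial-like cells the change from control differed in 1 gene on day 17 (Fosb, log2 difference -1.86; 514 genes at an unadjusted p under 0.05) and in 21 genes on day 23 by edgeR with Benjamini-Hochberg adjustment, 9 with a larger and 12 with a smaller log2 fold change in choroid plexus epithelial-like cells. Herpud1 (0.93) and Manf (0.79) had the larger change in choroid plexus epithelial-like cells, and Hsp90aa1 (-0.92) and Hsph1 (-1.03) the smaller. The count on day 17 was 7 without control mouse 2, 3 without day 23 mouse 1, 0 without control mouse 3, day 17 mouse 2 or day 17 mouse 3, and 20 without a filter on low counts. On day 23 it was 39, 35 and 32 without control mouse 1, day 17 mouse 1 and day 17 mouse 2, and 79 without a filter. Between smooth muscle-like and endothelial-like cells it differed in 1 gene on day 17 (Cxcl1, -4.19) and in 4 on day 23 (Cxcl1 -3.29, Ccn1 -1.74, Ier5 -1.35 and Fos -0.97). Here the count was 3 and 2 on day 17 without control mouse 3 and day 17 mouse 3, 17 on day 23 without day 23 mouse 2, and 38 and 26 without a filter. In pericyte-like cells 0 genes differed from endothelial-like cells on either day by edgeR (375 and 396 at an unadjusted p under 0.05); on day 23 it was 12, 3 and 1 genes without day 23 mouse 1, control mouse 3 and day 17 mouse 3, and without a filter 5 and 18 on the 2 days. DESeq2 was not run on these differences. The change from control differed between day 23 and day 17 in 1 gene in smooth muscle-like cells (Ccn1) and in 17 genes in choroid plexus epithelial-like cells; with a mouse left out these were 0 (without day 17 mouse 2) to 3 and 0 (without day 17 mouse 1) to 27. Fosb, Cxcl1, Ccn1, Ier5, Fos, Herpud1, Manf, Hsp90aa1 and Hsph1 were named here after their values were seen.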

How the results depend on the processing

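The TotalSeq names of the tag reference, the mouse number as a block, cells that neighbour tag doublets left out, the subclass fits, and the alternatives for smooth muscle-like and choroid plexus epithelial-like cells were chosen after seeing the data. Of 205 values of single named genes, 191 kept their direction and side of the threshold with library size alone and 202 with RLE size factors; of 172 with DESeq2 values, 149 did. By the TotalSeq names 74 of 190 did and 114 lost their call, and with each mouse left out in turn 1503 of 1836 did and 288 lost it. Scrublet marked no cell, so doublets by tags alone gave the same values. Depth limits pericyte-like cells most. Except where stated, the cause of a difference was not tested.

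Numbers of genes changed follow, for day 17 against control, day 23 against control and day 23 against day 17. In endothelial-like cells (36, 201 and 63) they were 311, 506 and 266 without a filter on low counts, 4, 30 and 6 by the TotalSeq names (8 mice, 2 of them controls), and 15, 49 and 37 in capillary-like cells alone, where fewer cells were tested. They were 45 (18 of them among the 36), 76 and 46 in venous-like cells alone and 3, 15 and 7 in arterial-like cells alone. On day 17 they were also 64 by DESeq2, 58 with at least 2000 UMIs, 67 with at most 5% mitochondrial UMIs and 16 without venous-like cells. With a mouse left out they ran from 17 (without control mouse 1) to 53, from 98 (without control mouse 1) to 211, and from 36 (without day 23 mouse 3) to 74. In pericyte-like cells (0, 0 and 0) they were 14, 39 and 64 without a filter, 14 (day 23 against control) and 3 (day 23 against day 17) with at least 500 UMIs, 12 with at least 2000 UMIs and 7 with at most 5% mitochondrial UMIs (both day 23 against control), 1 and 9 against control with neighbours of tag doublets left out, and 1 and 1 against control by the TotalSeq names. With a mouse left out they ran from 0 to 1 (without day 17 mouse 3), 0 to 4 (without day 17 mouse 1) and 0 to 3 (without day 17 mouse 3).

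In smooth muscle-like cells (0, 7 and 1) they were 40, 51 and 32 without a filter, 7, 12 and 34 in cells with matching tags, 4 by DESeq2 on day 23, 1 on day 17 with neighbours of tag doublets left out, and 1 and 0 against control by the TotalSeq names. With a mouse left out they ran from 0 to 1, from 2 (without control mouse 3 or day 23 mouse 3) to 9, and from 0 (without day 17 mouse 2) to 3. In choroid plexus epithelial-like cells (0, 98 and 17) they were 43, 282 and 83 without a filter, 1, 5 and 2 in cells with matching tags, 1, 17 and 2 by the TotalSeq names, 0 and 0 in the comparisons of day 23 by TotalSeq tags, 42 and 3 there with at most 5% mitochondrial UMIs, 6 (day 17) and 11 (day 23 against day 17) with library size alone, and on day 17 also 2 by DESeq2 and 4 with neighbours of tag doublets left out. With a mouse left out they ran from 0 to 22 (without control mouse 1), from 34 (without day 23 mouse 3) to 210 (without control mouse 1), and from 0 (without day 17 mouse 1) to 27 (without control mouse 2). Without a filter 3584 genes differed between endothelial-like and pericyte-like cells, against 2264.

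The mouse numbers share no stated litter or day, and same-numbered mice did not deviate together: their correlations ran from -0.102 to 0.0437 in endothelial-like, from -0.0776 to 0.0410 in choroid plexus epithelial-like, from -0.0977 to 0.0749 in smooth muscle-like and from -0.171 to 0.218 in pericyte-like cells. With the mouse number as a block the count was 61 against 36 for endothelial-like and 8 against 0 for choroid plexus epithelial-like cells on day 17, and the other counts moved by less than 1.5 times.

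Shares of choroid plexus epithelial-like cells differed by -2.13 percentage points (TotalSeq tags) and -2.43 (matching tags) between day 23 and control mice against -4.87, and by -1.44 and -1.94 between day 23 and day 17 against -3.72. The pericyte-like share differed by 0.362 (at least 500 UMIs), 0.603 (at least 2000 UMIs), 0.604 (TotalSeq tags) and 0.539 (matching tags) points between day 23 and control mice against 0.931. Gene lists called in endothelial-like cells were 2, 4 and 1 with an estimated correlation against 9, 10 and 11, and 2 on day 17 and 4 between day 23 and day 17 by fry. In pericyte-like cells they were 0 and 0 against 2 and 3 in the comparisons of day 23, with an estimated correlation and by fry, and 5 between day 23 and day 17 without a filter. Between endothelial-like and pericyte-like cells they were 0 against 14 with an estimated correlation. Among those with a single tag of each kind, matching tags made up 99.5% of CD45-negative cells at a quantile of 0.95, and 93.5% (MULTIseqDemux, where partners were not 1 to 1), 83.2% (at least 20 tag UMIs) and 90.6% (at least 200) of CD45-positive barcodes. The lowest share of a mouse among single-tag CD45-positive barcodes was 5.01% (quantile 0.95), 0% (MULTIseqDemux), 7.51% (at least 20) and 7.04% (at least 200), and the highest 30.6%, 20.5% and 18.9% for the last 3. Directions turned for Icam1 on day 17 (-0.14) and Plaur on day 23 (-0.0725) in capillary-like cells alone, and for Vcam1 between day 23 and day 17 without venous-like cells (0.43). In arterial-like cells alone, values that turned included Zic2 on day 17 (0.067). Between day 23 and day 17 they included Icam1 (-0.64 ± 0.31), Vcam1 (0.35 ± 0.23) and Foxq1 (-0.033).

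Of the 10 splits of the 6 mice of a comparison (5 where smooth muscle-like cells of day 17, from 2 mice, take part), too few for a share under 0.05, the real one called 36, 201 and 63 genes in endothelial-like cells and the highest other 1, 1 and 2. In pericyte-like cells these were 0, 0 and 0 against 19, 1 and 56, in smooth muscle-like cells 0, 7 and 1 against 1, 4 and 1, and in choroid plexus epithelial-like cells 0, 98 and 17 against 10, 2 and 2. What made other pericyte splits call 19 and 56 genes was not tested. As many genes as the real split came from 1 of the 10 splits in each endothelial-like comparison, from 10 in each pericyte-like one, from 10, 1 and 4 in smooth muscle-like and from 10, 1 and 1 in choroid plexus epithelial-like cells. Of 41 label arrangements between 2 classes within mice, only the real one reached 2264 genes for endothelial-like against pericyte-like cells (highest other 1459) and 1861 for arterial-like against venous-like cells (highest other 500). The classes were clusters of the same counts, so swapped labels were bound to call fewer genes. These arrangements therefore decide nothing about the classes.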

Other observations

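All tests in this part were chosen only after results had been seen. Choroid plexus epithelial-like cells, which make cerebrospinal fluid, held more RNA of protein folding genes of the endoplasmic reticulum on day 23 than in control mice. Manf, a factor secreted under stress of the endoplasmic reticulum, was at 357 ± 71.8 CPM against 145 ± 10.6 (mean ± SD, n = 3 mice each; log2 fold change 1.30 ± 0.12 SE), Hspa5, the main chaperone of that compartment, at 1092 ± 190 against 619 ± 32.4 (0.82 ± 0.09), Herpud1 at 115 ± 28.0 against 49.3 ± 5.79 and Creld2 at 62.9 ± 5.68 against 26.5 ± 10.5. Rsrp1 fell from 211 ± 28.6 to 76.1 ± 8.97 CPM. Of 8095 genes 98 passed by edgeR with Benjamini-Hochberg adjustment, 87 higher and 11 lower, against 31 and 44 with library size alone, which moved the median log2 fold change of all genes by -0.155. Of 20 named genes past the threshold 8 passed with each mouse left out (Hspa5, Rsrp1, Hspb1, Herpud1, Manf, P4ha1, Creld2 and Tmem50b), and the count was 34 without day 23 mouse 3, 44 without control mouse 2, 48 without day 23 mouse 1, 60 without day 23 mouse 2 and 210 without control mouse 1. By TotalSeq tags it was 0 and in cells with matching tags 5.

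Of 16 protein folding genes 8 rose in choroid plexus epithelial-like cells on day 23, with a median log2 fold change of 0.59 (fry, Benjamini-Hochberg adjusted p = 0.0016), and of 6 heat shock genes 3 rose (median 0.62; adjusted p = 0.0064). On day 17, 0 genes passed by edgeR (453 at an unadjusted p under 0.05; 2 by DESeq2), with Manf at 0.68 ± 0.12 and Hspa5 at 0.50 ± 0.09 (edgeR, Benjamini-Hochberg adjusted p = 0.054 for both). The protein folding list was already higher then, with 0 of 16 past the threshold and a median of 0.36 (fry, Benjamini-Hochberg adjusted p = 0.027), and in endothelial-like cells 3 of 17 rose on day 17 (median 0.22; adjusted p = 0.0019). Between day 17 and day 23, 17 genes passed, among them Manf (0.62 ± 0.12), the mitochondrial genes mt-Cytb (0.45) and mt-Co3 (0.42) and Rsrp1 (-0.86); none of 7 named genes passed without day 17 mouse 1, when the count was 0. It was 11, 10, 5, 3 and 27 without day 17 mouse 2, day 17 mouse 3, day 23 mouse 2, day 23 mouse 3 and control mouse 2. For day 17 against control it was 22, 5, 1, 7 and 2 without control mouse 1, control mouse 2, day 17 mouse 1, day 23 mouse 1 and day 23 mouse 2. Vtn, a pericyte gene, was at 89.1 ± 61.4 CPM on day 23 against 19.4 ± 8.23 in control mice, with overlapping mice. RNA of pericytes may thus have moved with this comparison, which 1 gene with overlapping mice cannot decide. In endothelial-like cells 6 of 17 protein folding genes rose on day 23 (median 0.29; fry, Benjamini-Hochberg adjusted p = 0.0017), 5 of 6 heat shock genes (median 1.10; adjusted p = 0.0017), 7 of 15 immediate early genes (median 0.26; adjusted p = 0.0074) and 0 of 7 clock genes (median 0.45; adjusted p = 0.052). In pericyte-like cells 0 of 6 heat shock genes passed on day 23, but the list was higher (median 0.70; fry, Benjamini-Hochberg adjusted p = 0.038), while 0 of 14 immediate early genes passed (median -0.18; adjusted p = 0.52). Manf lies at 106838312 to 106891979 of chromosome 9 (mm10).

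In smooth muscle-like cells 7 of 4260 genes passed on day 23 by edgeR with Benjamini-Hochberg adjustment. The matrix-associated genes Ccn2 and Ccn1, targets of YAP signalling, fell from 1298 ± 284 to 394 ± 122 CPM and from 849 ± 129 to 279 ± 104 CPM (mean ± SD, n = 3 mice each; log2 -1.72 ± 0.21 and -1.65 ± 0.21), Fos, an immediate early gene, fell by 0.57 on the log2 scale, the collagen gene Col8a1 by 1.33 and the chemokine gene Cxcl1 by 2.03, while Hsph1 (1.52 ± 0.27) and Hspb1 (0.65 ± 0.11) rose. Ccn1 and Ccn2 passed with each mouse left out, and 2 genes passed without control mouse 3 or without day 23 mouse 3. On day 17, with 2 mice, 0 genes passed by edgeR (229 at an unadjusted p under 0.05) or by DESeq2, and between day 17 and day 23 Ccn1 alone passed (-1.77 ± 0.22), not without day 17 mouse 2. Without day 17 mouse 3, day 23 mouse 1 or day 23 mouse 2 the last count was 2, 3 and 3, and on day 17 it was 1 without control mouse 1 or day 17 mouse 3. The TGF-beta and mesenchymal list, which holds Ccn1 and Ccn2, was lower on day 23 (2 of 15 fell over all genes and adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.010; adjusted p = 0.17 with an estimated correlation).

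A candidate explanation for lower Cirbp with higher heat shock genes in endothelial-like cells on day 23 is a response shared by other cell classes, such as a difference in body temperature, since cold raises and warmth lowers Cirbp and Rbm3. Of 4 values of these genes in smooth muscle-like and choroid plexus epithelial-like cells, 3 were lower on day 23 at an unadjusted p under 0.05 by edgeR, which goes with a shared response: Cirbp at -1.01 ± 0.29 and Rbm3 at -0.47 ± 0.19 in smooth muscle-like cells and Cirbp at -0.71 ± 0.19 in choroid plexus epithelial-like cells, while Rbm3 was at 0.10 ± 0.14 there. None of these 4 values passed over all genes (edgeR, Benjamini-Hochberg adjusted p from 0.072 to 0.85). In pericyte-like cells, outside that count, Rbm3 was at -1.21 ± 0.25 and Cirbp at -0.30 ± 0.34 (edgeR, Benjamini-Hochberg adjusted p = 0.090 and 0.96). On day 17 Cirbp was already lower in endothelial-like cells (-0.52 ± 0.10). The heat shock list was not called then, with 1 of 6 genes rising and a median of 0.12 (fry, Benjamini-Hochberg adjusted p = 0.56). The gene that rose was Hspa8 (0.43 ± 0.09), while Hspa1b fell in capillary-like cells alone (-0.57 ± 0.12, edgeR, Benjamini-Hochberg adjusted p = 0.022). A list that is not called cannot show that its genes did not change, so day 17 does not decide whether both changed together. Body temperature was not measured in the data used here.

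Of 20 clusters, 2 stayed unnamed: 1 of 47 cells with a median of 1595 UMIs, in which markers of olfactory ensheathing cells led, and 1 of 62 cells in which microglia markers led, with Ccl4, Ccl5, Lyz2 and C1qa among its leading genes in spite of the sort against CD45. A cluster of 288 endothelial-like cells was led by the interferon genes Ifit1, Ifit3, Usp18 and Isg15, and a cluster of 788 by the immediate early genes Atf3, Ccn1 and Fos. An unnamed endothelial subcluster of 65 cells had the pericyte markers Vtn, Rgs5, Ndufa4l2 and Higd1b among its leading genes. It stayed in the endothelial-like sums.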
